A study of Mus musculus with 50 samples.

How the data were processed

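RNA of mouse ES and EG cell lines (36 arrays in the first set and 14 in the second, LIF+ only) was labelled with Cy3 and hybridised against a reference pool of RNA from cultured mouse cell lines labelled with Cy5, without dye swap. Scans were read by the authors with Agilent Feature Extraction A.7.5.1, the version per the file headers. The deposited scanner files hold spot and background intensity in both channels before and after processing, an intensity scale per the file headers, and a log10 ratio of reference over sample, also per the file headers. They further hold 0 or 1 flags per spot (saturated, well above background), a unit of another kind (other) per the file headers. The deposited value tables hold 28852 and 29138 probes on a log10 scale. They were checked against the scanner files: 98.5% and 99.6% of differences between arrays equal those of the log10 ratio within 0.001. How the authors set the level of each probe is not stated, so these tables served as an alternative only.

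Spot and background intensities were corrected with normexp (offset 50) and loess-normalised within arrays in limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table version 1.17.8), as log2 ratios of sample over reference. A probe was kept when its Cy3 signal was well above background on a share of at least 0.5 of the arrays of at least 1 group, a filter that removed no named probe. Of the negative controls 10.8% to 100% per array carried the same flag in the first set and 99.7% to 100% in the second. The flag thus does not show that a gene was expressed, and small changes of dim genes may lie near the floor. Probes were named through accessions in the gene table supplied. Named this way were 15294 of 41006 in the first set and 14758 of 42006 in the second, and the rest were left out of the gene comparisons. Nanog, Gata4, Gata6, Rarb, H19, Meg3 and Xist got no probe this way and were not analysed. For 2782 genes with more than 1 probe in the first set, the brightest was used. No position beyond the chromosome was available.

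Signal over background limits what arrays can show. In the first set 93.4% to 98.7% of probes exceeded the 0.95 quantile of negative controls, and in the second 90.8% to 98.5%. Genes under the negative controls on most arrays numbered 131 and 234, and genes with saturated spots on every array of a group 51 and 24. Their changes are compressed.

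The choices in this paragraph were made before the data were examined. Treatments were tested with limma (lmFit, eBayes) on the first set, with the cell line as a fixed block and separate treatment terms for ES and EG lines. The difference between these terms was tested as an interaction. Origin, strain (C57BL/6 or 129) and labelled sex were tested on LIF+ arrays of each set apart, with origin and strain in 1 fit and both as covariates of sex, and repeat arrays of a line averaged. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. Fold changes are log2 with SE from the fit. For treatments ES and EG lines share 1 residual error per gene, so this SE is not the spread of the 6 lines of an origin. Overlaps of calls are given with the number that independent lists would share. The shared LIF+ arrays were addressed with simulations without change and partings of the lines, as planned, and their number (20 each) was set while the scripts were written. Named genes were, per contrast, up to 10 higher and 10 lower with the largest change among those that passed with the same direction in every line (treatments) or without overlap of groups after the covariate. Up to 4 members of each list with the smallest adjusted p were added, and always Pou5f1, Sox2, Klf4, Socs3 (LIF), Cyp26a1 (retinoic acid), Sox17, Fgf5 and T (both treatments) and Dazl, Ddx4 and Igf2 (other contrasts). The text may omit those last in each ranking, and some genes that the rule selects are not reported here.

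The 17 gene lists were LIF and STAT3 targets, pluripotency, primed epiblast, mesoderm and streak, Nodal and BMP targets, FGF and ERK feedback, retinoic acid targets, Hox clusters, primitive endoderm, trophectoderm, neural, germ cell, fibroblast feeder, cell cycle, p53 stress, imprinted and Y-linked genes. Primitive endoderm, primed epiblast, mesoderm, neural, trophectoderm, germ cell and feeder lists mark other cell types that cultures could hold. Of their genes 1 of 23 primitive endoderm, 4 of 15 trophectoderm and 0 of 22 feeder genes also stand in another list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 17 lists of a contrast, and again with an estimated correlation. Of 204 tests camera called 51, and 5 held with an estimated correlation. These were primed-epiblast genes and LIF and STAT3 targets after LIF withdrawal in EG lines, pluripotency genes and retinoic acid targets with retinoic acid in ES lines, and retinoic acid targets in EG lines. The median, mean and test of a list differed in sign in 43 tests and in 0 of those called.

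The fits were tested on simulated data with 200 changed genes each. Of changes of log2 size 1 they recovered 100% for treatments and at least 92.5% for origin, strain and sex, and of size 0.5 they recovered 94.0% for LIF withdrawal, 83.6% for the retinoic acid interaction and 61.2% to 79.1% for origin, strain and sex. Pairing by line was checked over genes centred on the mean of each origin and condition. The lowest correlation between conditions of 1 line was 0.311 and the mean 0.676, and the mean with other lines of the same origin was -0.133. The centring makes that last value negative whenever the mean within a line is positive, so only the values within lines bear on the pairing. Alternatives covered background correction, Feature Extraction ratios, Cy3 alone, the authors' table, filters, probe choice, the line block, labelling kit, extraction day, covariates, subsets of lines and leaving out each line. The extraction day is the day on which Feature Extraction read the scan, per the file headers, and not a day of RNA extraction. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15, numpy 2.4.6).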

Results

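RNA from mouse embryonic stem (ES) lines and embryonic germ (EG) lines was measured on 2-colour oligonucleotide arrays. ES lines derive from the early embryo and EG lines from primordial germ cells. In the first array set, 6 ES lines (MG1.19, ES-C57BL/6, CC9.3.1, EBRTcH3, D3-GL and 129.3) and 6 EG lines (TGC 8-8, TGC 8.5-5, EG-1, EG-3, TGC 8-7 and TGC 12-8) were each grown in 3 conditions, which gave 36 arrays. The conditions were medium with leukaemia inhibitory factor (LIF+), medium without it (LIF-), and LIF with all-trans retinoic acid (LIF+RA). The second array set held 14 LIF+ arrays, 8 of ES and 6 of EG lines, on another array design. The cell line was the replicate throughout, and precision was limited by the number of arrays. Median Cy3 signal of the arrays ran from 466 to 761 in the first set and from 516 to 607 in the second. A gene symbol could be given to 15294 of 41006 probes in the first set, so 12254 genes were compared there and 12058 in the second.

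Across the 36 arrays, treatment took 34.7% of the sums of squares over 11970 genes, and cell line within origin and strain took 29.8%. Strain took 12.1%, origin 11.2%, the treatment-by-origin term 2.19% and the residual 10.00%. These shares describe the data and carry no test. Origin was entered before strain, and the strains are spread unevenly over the origins, so the shares of origin and strain depend on that order. Labelling kit and extraction day varied with origin and are not separated from it. No extraction day of these arrays held lines of both strains, so day is not separated from strain either.

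The LIF- arrays ask which genes depend on LIF in ES lines. Socs3, the feedback inhibitor of the LIF receptor pathway, fell by 2.14 ± 0.18 on the log2 scale (SE, n = 6 lines, adjusted p = 2.96e-07), and the pluripotency factor Klf4 fell by 2.51 ± 0.32, both in 6 of 6 lines. Nr0b1 (Dax1), a nuclear receptor of the naive state, fell by 2.72 ± 0.26, Tcl1 by 2.05 ± 0.27 and Klf2 by 1.59 ± 0.18. Markers of the postimplantation epiblast and of the primitive streak rose in 6 of 6 lines: Fgf5 by 2.28 ± 0.34, T (Brachyury) by 1.52 ± 0.32 and Wnt3 by 1.42 ± 0.20. Pou5f1 (Oct4) changed by 0.11 ± 0.15 (adjusted p = 0.703, higher in 4 of 6 lines), whereas Sox2 fell by 0.60 ± 0.16 (adjusted p = 0.0085, 6 of 6 lines).

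In the list of LIF and STAT3 targets, 6 of 14 measured genes fell in ES lines and 0 rose, among them Gbx2 (-0.71) and Pim3 (-0.67), which is 6 lower and 1 higher adjusted over the list alone. That list was lower than other genes (camera adjusted p = 0.0021), with adjusted p = 0.107 with an estimated correlation. Of 23 pluripotency genes 11 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 7.41e-06, adjusted p = 0.107 with an estimated correlation). The riser was Lin28a, an RNA-binding protein (0.46 ± 0.08, adjusted p = 0.000341); members that moved against their list are named here and further on, after their values were seen. Among 10 primed-epiblast genes 7 rose and 0 fell, as did 7 and 0 adjusted over the list alone, including Otx2 (0.68 ± 0.15). Their camera adjusted p was 5.89e-05 (adjusted p = 0.113 with an estimated correlation). Of 18 mesoderm and streak genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Fgf8 at 1.36 ± 0.19 and Wnt8a at 1.30 ± 0.23 (camera adjusted p = 0.000164; adjusted p = 0.174 with an estimated correlation); the faller was Mesp2 (-0.11 ± 0.04). Of 13 Nodal and BMP targets 5 rose and 0 fell, both over all genes and adjusted over the list alone, with Msx1 at 1.48 ± 0.15 and Fst at 1.24 ± 0.18 (camera adjusted p = 0.000913; adjusted p = 0.107 with an estimated correlation). Among 26 germ-cell genes 5 fell and 0 rose, with the same counts adjusted over the list alone, Dppa3 (Stella) by -0.69 ± 0.16 in 5 of 6 lines (camera adjusted p = 0.00615; adjusted p = 0.174 with an estimated correlation). The other 11 lists were not called, the lowest adjusted p being 0.103 for imprinted genes. In the uncalled neural list 2 of 18 genes rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.3), the fallers including Tubb3 (-1.13 ± 0.16) and Neurod1 (-0.97 ± 0.17).

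Other genes with large changes after LIF withdrawal in ES lines were the immunoproteasome subunit Psmb8 (1.69 ± 0.26), the chemokine Cxcl10 (1.49 ± 0.35) and the surface protein Prom1 (1.41 ± 0.15), each higher in 6 of 6 lines. Dusp6, a feedback phosphatase of ERK, rose by 0.95 ± 0.16. Morc1, a silencer of transposons in germ cells, fell by 2.25 ± 0.21 and the secreted protein Spp1 by 1.96 ± 0.24. Falls were also seen for the unconventional myosin Myo1f by 2.17 ± 0.30, the basement membrane chain Lama1 by 1.55 ± 0.21 and the ribosomal protein paralogue Rpl39l by 1.79 ± 0.20. In total 2439 genes passed an adjusted p of 0.05 (limma), 1448 higher and 991 lower, of which 90 changed by over 2-fold and 1838 moved the same way in all 6 lines. A second probe for Fgf5 gave 0.73 and a second probe for T gave 2.21, so their sizes depend on the probe. Without the cell line as a block 421 genes passed.

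**Figure D1:**
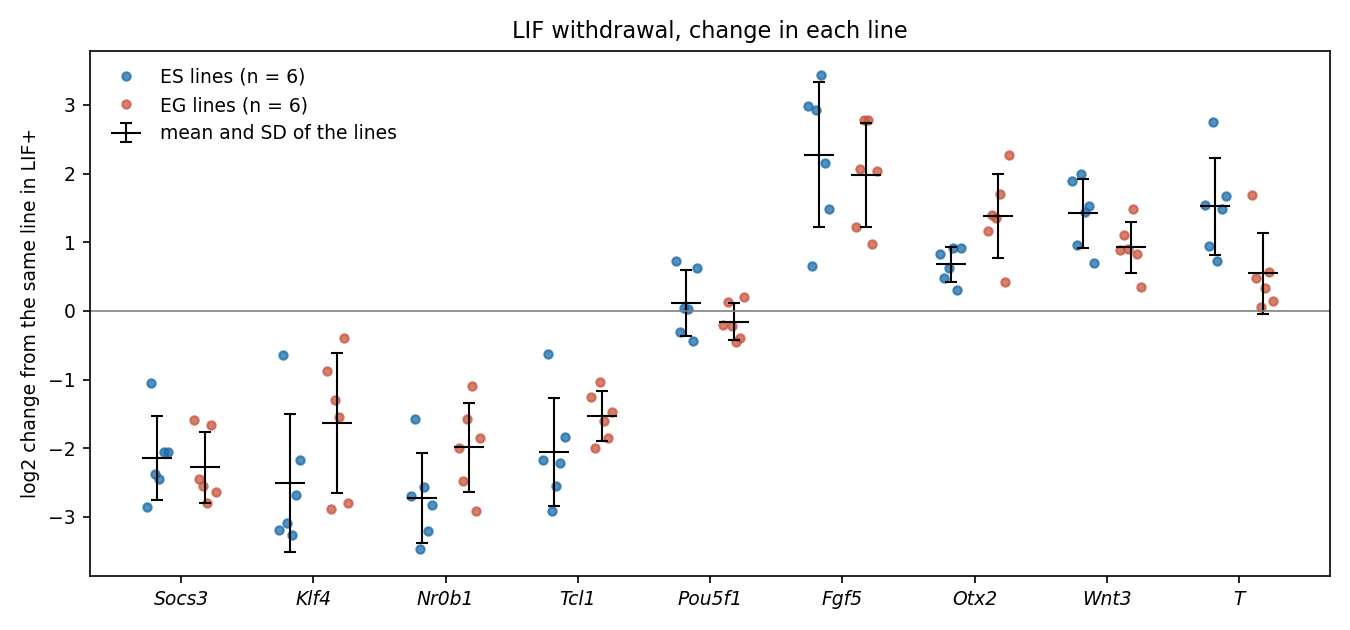
Log2 change from LIF+ to LIF- for 9 genes (vertical axis) in each ES line (blue points) and each EG line (red points), with the mean and SD of the 6 lines in black. Socs3, Klf4, Nr0b1 and Tcl1 lie below 0 in every line and Fgf5, Otx2 and Wnt3 above 0, while Pou5f1 lies on both sides of 0.

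EG lines showed the same kind of response to LIF withdrawal, asked with the same contrast over the 6 EG lines. Socs3 fell by 2.28 ± 0.18 (SE, n = 6 lines, adjusted p = 8.05e-08), Nr0b1 by 1.99 ± 0.26, Klf4 by 1.63 ± 0.32 and Klf5, another factor of the naive network, by 1.16 ± 0.16, each in 6 of 6 lines. Fgf5 rose by 1.98 ± 0.34, the zinc finger factor Sall2 by 1.69 ± 0.27 and Otx2, a regulator of the primed state, by 1.39 ± 0.15, again in 6 of 6 lines. Pou5f1 stood at -0.16 ± 0.15 (adjusted p = 0.588, lower in 4 of 6 lines), Sox2 at -0.39 ± 0.16 (adjusted p = 0.109, lower in 6 of 6) and T at 0.54 ± 0.32 (adjusted p = 0.309, higher in 6 of 6), and these values did not pass.

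The primed-epiblast list was higher in EG lines without LIF, with 7 of 10 genes up and 0 down (9 and 0 adjusted over the list alone; camera adjusted p = 9.16e-08, and adjusted p = 0.047 with an estimated correlation). LIF and STAT3 targets were lower, with 7 of 14 down and 0 up, also adjusted over the list alone (camera adjusted p = 3.14e-05; adjusted p = 0.0373 with an estimated correlation). Of 23 pluripotency genes 9 fell and 1, Lin28a, rose by 0.44 ± 0.08 (12 and 1 adjusted over the list alone; camera adjusted p = 5.68e-05, adjusted p = 0.158 with an estimated correlation). Of 13 Nodal and BMP targets 4 rose and 0 fell (6 and 0 adjusted over the list alone), Fst by 0.80 ± 0.18 and Msx1 by 0.59 ± 0.15 (camera adjusted p = 0.000499; adjusted p = 0.0589 with an estimated correlation). Of 18 mesoderm and streak genes 4 rose and 0 fell, the same adjusted over the list alone, Wnt8a by 1.13 ± 0.23, Wnt3 by 0.92 ± 0.20 and Fgf8 by 0.64 ± 0.19 (camera adjusted p = 0.0452; adjusted p = 0.476 with an estimated correlation). Cell-cycle genes fell in 6 of 18 cases and rose in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00545, adjusted p = 0.347 with an estimated correlation). Germ-cell genes fell in 4 of 26 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.0255; adjusted p = 0.303 with an estimated correlation). Imprinted genes rose in 5 of 28 cases and fell in 1, Slc22a18 at -0.27 ± 0.08 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.169 with an estimated correlation). The other 9 lists were not called, the lowest adjusted p being 0.107 for the fibroblast feeder markers.

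Further changes in EG lines without LIF were a fall of Hmces, a protein of DNA repair, at -1.4998 ± 0.1007 (adjusted p = 3.48e-09). Falls were also seen for Morc1 by 1.55 ± 0.21, Myo1f by 1.70 ± 0.30, Tcl1 by 1.53 ± 0.27, Lama1 by 1.03 ± 0.21 and Lamc1 by 0.55 ± 0.07. Cxcl12, a chemokine, rose by 1.07 ± 0.17 and the interferon-induced GTPase Irgm1 by 1.06 ± 0.22, each in 6 of 6 lines. In all, 1816 genes passed (903 higher, 913 lower), 34 of them with over 2-fold change, and 1553 moved the same way in all 6 EG lines. Without the cell line as a block 152 passed.

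No gene distinguished the LIF response of EG lines from that of ES lines. In the limma test of the difference 0 genes passed, with 981 at an unadjusted p under 0.05 and a lowest adjusted p of 0.391. The difference (EG minus ES) was 0.88 ± 0.45 for Klf4 (adjusted p = 0.66), 0.71 ± 0.21 for Otx2 (adjusted p = 0.42), 0.87 ± 0.22 for Tubb3 (adjusted p = 0.391) and -0.98 ± 0.46 for T (adjusted p = 0.619). Mesoderm and streak genes rose less in EG lines as a list (camera adjusted p = 0.00984; adjusted p = 0.642 with an estimated correlation), although 0 of its 18 genes passed singly and 1 was lower adjusted over the list alone. The other 16 lists were not called, and the lowest adjusted p was 0.0664 for neural genes. Of the called genes 696 were higher in both origins (107 for independent lists), 545 were lower in both (73.8 for independent lists) and 0 were opposite. Across genes the fold changes correlated with Pearson r = 0.837 and Spearman rho = 0.642, where genes are not independent replicates. The changes were smaller in EG lines over all genes, with an SD of 0.183 against 0.225 and a slope of EG on ES changes of 0.681. Whether the smaller rise of the mesoderm and streak list follows this general difference was not tested.

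Retinoic acid in the presence of LIF asks which genes respond to a differentiation signal. In ES lines the Hox cofactor Meis1 rose by 3.20 ± 0.13 on the log2 scale (SE, n = 6 lines, adjusted p = 1.12e-14), Meis2 by 3.08 ± 0.19 and the retinoid-degrading enzyme Cyp26a1 by 2.36 ± 0.23, each in 6 of 6 lines. The largest rises were those of the myelin protein Pmp22, 4.74 ± 0.14 or 26.7-fold, and of Adgra2, a receptor of Wnt signalling, 3.64 ± 0.15. Pou5f1 fell by 1.66 ± 0.15 (adjusted p = 4.29e-09), Sox2 fell by 1.40 ± 0.16 and Nr0b1 fell by 2.85 ± 0.26, all in 6 of 6 lines. Klf4 fell by 0.87 ± 0.32 (adjusted p = 0.0286, 6 of 6 lines).

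Of 14 retinoic acid targets 10 rose in ES lines and 0 fell, also adjusted over the list alone (camera adjusted p = 3.6e-05; adjusted p = 0.011 with an estimated correlation). Of 23 pluripotency genes 21 fell and 1 rose (22 and 1 adjusted over the list alone; camera adjusted p = 8.9e-09, adjusted p = 0.0436 with an estimated correlation). The riser was Dppa5a (0.47 ± 0.16, adjusted p = 0.0189), a gene with saturated spots whose value turned to -0.51 from the Cy3 channel alone. In the Hox clusters 16 of 24 genes rose and 1 fell, the same adjusted over the list alone, with Hoxa7 at 2.38 ± 0.09 and the faller Hoxa6 at -0.07 ± 0.02 (camera adjusted p = 0.000264; adjusted p = 0.1 with an estimated correlation). Cell-cycle genes fell in 15 of 18 cases and rose in 0, the same adjusted over the list alone, by small amounts such as -0.48 ± 0.05 for Pcna and -0.61 ± 0.07 for Ccne1 (camera adjusted p = 2.58e-05; adjusted p = 0.1 with an estimated correlation). In the FGF and ERK feedback list 7 of 10 genes fell, Etv5 by 2.18 ± 0.14, and 2 rose, Phlda1 by 2.13 ± 0.20 and Dusp6 by 0.94 ± 0.16, the same adjusted over the list alone (camera adjusted p = 0.0249; adjusted p = 0.277 with an estimated correlation).

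Markers of other cell types moved with retinoic acid in ES lines. Of 19 primitive endoderm genes 14 rose and 1 fell, the same adjusted over the list alone, with Plat at 2.36 ± 0.16, Foxa2 at 1.91 ± 0.15, Sox17 at 1.13 ± 0.20 and the faller Hnf4a at -0.14 ± 0.05 (camera adjusted p = 0.000264; adjusted p = 0.1 with an estimated correlation). Of 12 trophectoderm genes 6 rose and 1 fell, the same adjusted over the list alone, with Esx1 at 3.06 ± 0.16, Gata3 at 2.04 ± 0.16, Gata2 at 1.65 ± 0.15 and the faller Tfap2c at -0.51 ± 0.14 (camera adjusted p = 0.00364; adjusted p = 0.1 with an estimated correlation). Of 14 fibroblast feeder markers 9 rose and 0 fell, the same adjusted over the list alone, with Tagln at 2.11 ± 0.21 and Pdgfrb at 1.61 ± 0.14 (camera adjusted p = 0.00189; adjusted p = 0.149 with an estimated correlation). Primed-epiblast genes fell in 6 of 10 cases, Otx2 by 1.86 ± 0.15, and rose in 2, Cldn6 by 0.43 ± 0.12 and Sall2 by 0.69 ± 0.27, the same adjusted over the list alone (camera adjusted p = 0.0436; adjusted p = 0.352 with an estimated correlation). Fgf5 fell by 0.87 ± 0.34 (adjusted p = 0.0414, 4 of 6 lines) and T by 0.82 ± 0.32 (adjusted p = 0.0408, 6 of 6 lines). Imprinted genes rose in 13 of 28 cases and fell in 3, the same adjusted over the list alone, with Dlk1 at 2.21 ± 0.16 and Igf2r, the receptor that clears IGF2, at 1.15 ± 0.10. The fallers were Snrpn at -0.59 ± 0.07, Phlda2 at -0.20 ± 0.07 and Osbpl5 at -0.10 ± 0.03, which turned to 0.25 as a mean of its probes (camera adjusted p = 0.0436; adjusted p = 0.153 with an estimated correlation). The other 7 lists were not called, the lowest adjusted p being 0.155 for Y-linked genes.

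Further genes that fell had changes of -3.13 ± 0.20 for Slc7a3, -2.66 ± 0.16 for Slc6a15, -2.40 ± 0.16 for threonine dehydrogenase Tdh and -2.62 ± 0.21 for Morc1, each in 6 of 6 lines. In total 5640 genes passed in ES lines (3163 higher, 2477 lower), 463 of them with over 2-fold change, and 4324 moved the same way in all 6 lines. Without the cell line as a block 3035 passed. The second probe of Cyp26a1 gave 3.04.

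**Figure D2:**
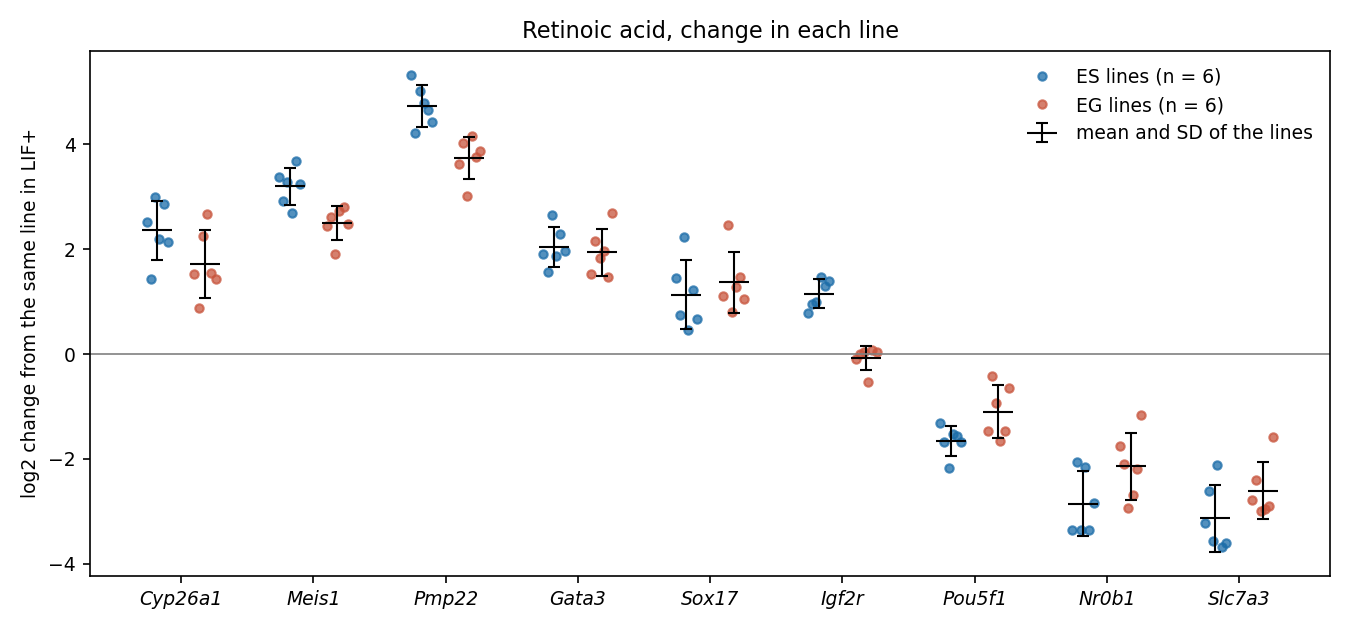
Log2 change from LIF+ to LIF+RA for 9 genes (vertical axis) in each ES line (blue points) and each EG line (red points), with the mean and SD of the 6 lines in black. Meis1 rose by 3.20 in ES and 2.50 in EG lines, whereas Igf2r rose in every ES line and lay between -0.52 and 0.07 in the EG lines.

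In EG lines retinoic acid raised many of the genes named for ES lines. Meis2 rose by 2.62 ± 0.19 (SE, n = 6 lines, adjusted p = 3.75e-10), Meis1 by 2.50 ± 0.13 and Cyp26a1 by 1.72 ± 0.23. Pmp22 rose by 3.74 ± 0.14 and Adgra2 by 2.37 ± 0.15. These rises were seen each in 6 of 6 lines. The Wnt inhibitor Dkk1 rose by 2.33 ± 0.16, and Tcstv3 and Tcstv1, members of a gene cluster active in 2-cell embryos, by 2.94 ± 0.45 and 2.33 ± 0.32, also in 6 of 6 lines. Pou5f1 fell by 1.09 ± 0.15 (adjusted p = 3.34e-06), Sox2 by 0.81 ± 0.16 and Nr0b1 by 2.14 ± 0.26 in 6 of 6 lines. Klf4 stood at -0.64 ± 0.32 (adjusted p = 0.115, lower in 6 of 6 lines) and T at -0.74 ± 0.32 (adjusted p = 0.0712, lower in 6 of 6), while Fgf5 fell by 1.43 ± 0.34 (adjusted p = 0.00155, 5 of 6 lines).

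Of 14 retinoic acid targets 9 rose in EG lines and 0 fell, the same adjusted over the list alone (camera adjusted p = 1.99e-05; adjusted p = 0.00853 with an estimated correlation). Of 23 pluripotency genes 17 fell and 1, Dppa5a, rose by 0.56 ± 0.16, or -0.09 from the Cy3 channel alone (18 and 1 adjusted over the list alone; camera adjusted p = 3.46e-06, adjusted p = 0.0889 with an estimated correlation). Hox genes rose in 16 of 24 cases and fell in 2, the same adjusted over the list alone, with Hoxa7 at 2.72 ± 0.09 and Hoxc9 at 1.36 ± 0.10. The fallers were Hoxa13 at -0.11 ± 0.04 and Hoxc5 at -0.09 ± 0.03 (camera adjusted p = 7.32e-06; adjusted p = 0.0889 with an estimated correlation). Cell-cycle genes fell in 10 of 18 cases and rose in 0 (12 and 0 adjusted over the list alone), Pcna by 0.48 ± 0.05 and Ccne1 by 0.54 ± 0.07 (camera adjusted p = 0.000551; adjusted p = 0.192 with an estimated correlation). FGF and ERK feedback genes fell in 7 of 10 cases, Etv5 by 1.74 ± 0.14, and rose in 1, Phlda1 by 1.47 ± 0.20, the same adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.247 with an estimated correlation). Nodal and BMP targets rose in 6 of 13 cases and fell in 1, Tdgf1 by 0.64 ± 0.21, the same adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.192 with an estimated correlation).

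Among markers of other cell types in EG lines, 11 of 19 primitive endoderm genes rose and 1 fell, the same adjusted over the list alone, with Foxa2 at 1.42 ± 0.15, Sox17 at 1.37 ± 0.20 and the faller Hnf4a at -0.12 ± 0.05 (camera adjusted p = 0.000903; adjusted p = 0.166 with an estimated correlation). Of 12 trophectoderm genes 7 rose and 1 fell, the same adjusted over the list alone, with Esx1 at 2.86 ± 0.16, Gata3 at 1.94 ± 0.16, Gata2 at 1.71 ± 0.15 and the faller Tfap2c at -0.51 ± 0.14 (camera adjusted p = 0.00125; adjusted p = 0.0889 with an estimated correlation). Of 14 fibroblast feeder markers 8 rose and 0 fell, the same adjusted over the list alone, with Pdgfrb at 1.51 ± 0.14 and Tagln at 1.43 ± 0.21 (camera adjusted p = 0.0317; adjusted p = 0.276 with an estimated correlation). The other 8 lists were not called, the lowest adjusted p being 0.0592 for LIF and STAT3 targets, although Otx2 of the primed list fell by 1.57 ± 0.15. Changes were -2.60 ± 0.20 for Slc7a3, -2.40 ± 0.16 for Slc6a15 and -2.22 ± 0.23 for the hormone gene Trh. In total 5155 genes passed (2761 higher, 2394 lower), 238 of them with over 2-fold change, 4173 moved the same way in all 6 EG lines, and without the cell line as a block 2242 passed.

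Tested singly, the retinoic acid responses of EG and ES lines differed past the threshold at 90 of 12254 genes. Changes over all genes were also smaller in EG lines, with an SD of 0.330 against 0.407 in ES lines. The slope of EG on ES changes was 0.752, a value that error in the ES changes also lowers. Whether genes and lists that changed less in EG lines follow this general difference was not tested. Igf2r, an imprinted gene on chromosome 17, rose by 0.78 to 1.48 in the 6 ES lines and changed by -0.52 to 0.07 in the 6 EG lines, a difference of -1.23 ± 0.14 (SE, n = 12 lines, adjusted p = 6.8e-05). The matricellular protein Smoc2 differed by -1.46 ± 0.20 (adjusted p = 0.00155) and Pmp22 by -0.996 ± 0.191 (adjusted p = 0.0145). The pentraxin Ptx3 differed by -0.98 ± 0.17 (adjusted p = 0.00883), the stress-response gene Ier3 by -1.30 ± 0.26 (adjusted p = 0.017) and the small GTPase Rhoc by -0.85 ± 0.15 (adjusted p = 0.00883). Each of these genes rose less in EG than in ES lines or did not pass there. Hoxc9 rose more in EG lines, by 0.81 ± 0.15 (adjusted p = 0.0105). Cyp26a1 differed by -0.64 ± 0.32 (adjusted p = 0.452), Pou5f1 by 0.56 ± 0.22 (adjusted p = 0.262) and Sox2 by 0.59 ± 0.23 (adjusted p = 0.262).

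As a list, pluripotency genes fell less in EG lines (camera adjusted p = 1.71e-05; adjusted p = 0.267 with an estimated correlation), with 0 of 23 past the threshold singly and 1 higher adjusted over the list alone. Fibroblast feeder markers rose less (camera adjusted p = 0.00454; adjusted p = 0.267 with an estimated correlation), with 0 of 14 past the threshold and 2 lower adjusted over the list alone. Calls for cell-cycle genes (adjusted p = 0.0169), Nodal and BMP targets (adjusted p = 0.0392) and primed-epiblast genes (adjusted p = 0.0392), all in the direction of higher values in EG lines, had 0 genes past the threshold and gave adjusted p = 0.343, adjusted p = 0.267 and adjusted p = 0.343 with an estimated correlation. The other 12 lists were not called, the lowest adjusted p being 0.0558 for Y-linked genes. In total 90 genes passed, 9 higher and 81 lower in EG lines, and 1439 had an unadjusted p under 0.05. Leaving out 1 line gave 18 to 228: 18 without TGC 8.5-5, 19 without D3-GL, 20 without TGC 12-8, 24 without MG1.19, 24 without CC9.3.1, 47 without EG-1, 51 without 129.3, 143 without EG-3 and 228 without ES-C57BL/6, a line of doubtful identity. The Cy3 channel alone gave 9 genes and no background correction 35. The count was 19 with strain by treatment in the fit, 13 of them among the 90, and 5 with the labelling kit by treatment and 0 without the 4 EG lines of the low-input kit. By protocol EG lines received 2 µM and 4 of the ES lines 1 µM retinoic acid at different plating densities, so dose, density and origin cannot be told apart. Strain also varied with origin and was not a term of the test that gave 90 genes. Of the genes called in either origin, 2448 were higher in both (713 for independent lists), 1813 lower in both (484 for independent lists) and 1 was opposite, with Pearson r = 0.929 and Spearman rho = 0.869 across genes.

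LIF withdrawal and retinoic acid moved overlapping genes. In ES lines 930 genes were higher under both treatments where independent lists would share 374, and 578 were lower under both where 200.3 would be shared, while 257 moved in opposite directions. Nr0b1 and Morc1 fell under both treatments, and Fgf5, T and Otx2 rose without LIF and fell with retinoic acid. In EG lines 546 genes were higher under both (203 for independent lists), 502 lower (178) and 164 opposite. Both contrasts share the LIF+ arrays, and simulated groups without change gave a covariance of fold changes of 0.00255 in ES and 0.00252 in EG lines, against 0.0366 and 0.0227 in the data. With the lines parted so that no LIF+ array was shared, the covariances were 0.0333 and 0.0218, and the overlaps had medians of 381 higher and 202 lower in ES and 105.5 and 110.5 in EG lines, where independent lists would share 135, 66.7, 35.5 and 28.6.

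EG and ES lines kept in LIF were compared to ask how cells of different origin differ in the undifferentiated state, with strain in the fit. Genes higher in EG lines in the first array set included Zfp74 by 1.43 ± 0.30 (SE, n = 12 lines, adjusted p = 0.0377), Zfp866 by 1.36 ± 0.25, Zfp53 by 1.31 ± 0.27 and Zfp825 by 1.17 ± 0.19. The glutathione-degrading enzyme Chac1 was higher by 1.33 ± 0.25 and the cysteinyl-tRNA synthetase Cars by 1.15 ± 0.23. Zrsr1, a paternally expressed imprinted gene on chromosome 11, was higher by 1.10 ± 0.15 (adjusted p = 0.0181) and the cyclin Ccnd3 by 1.12 ± 0.20. Id2, a BMP target, was lower by -1.12 ± 0.21 (adjusted p = 0.0291), as were Mal (-1.33 ± 0.28), Tma7 (-1.07 ± 0.16) and the translation factor Eif1 (-0.89 ± 0.11). For each of these genes the ES and EG lines did not overlap after the strain term, which the rule for named genes required. Of all 12254 genes 834 did not overlap, and of the 370 that passed 329. Pluripotency and germ-cell genes did not pass: Pou5f1 differed by 0.73 ± 0.25 (adjusted p = 0.107), and Sox2 by -0.22 ± 0.17 (adjusted p = 0.472). Klf4 differed by 0.08 ± 0.38 (adjusted p = 0.924), Dazl by 0.71 ± 0.21 (adjusted p = 0.0731) and Ddx4 by -0.30 ± 0.20 (adjusted p = 0.397).

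In total 370 genes passed in the first set, 285 higher and 85 lower in EG lines, 22 of them with over 2-fold change, and 0 of 17 lists was called (lowest adjusted p = 0.302, LIF and STAT3 targets). The count was 0 with the labelling kit as a covariate and 1 from the Cy3 channel alone. Leaving out 1 line gave 0 to 1049 genes: 0 without EG-1 and without EG-3, 35 without D3-GL, 39 without 129.3, 47 without CC9.3.1, 135 without MG1.19, 180 without TGC 8-7, 617 without TGC 8.5-5 and 1049 without TGC 8-8. It was 646 without ES-C57BL/6, the only C57BL/6 ES line of the set, whose identity is in doubt, as its profile was unlike ES-C57BL6.9 of the second set (r = 0.0536) and closest to the EG line TGC 8-8 (r = 0.695). Of the EG lines, TGC 8-8 and TGC 8.5-5 had the standard kit of the ES lines and the others the low-input kit. The count rose without either standard-kit EG line, and was lower or near 370 without a low-input one (381 without TGC 12-8). EG-1 and EG-3 are also the only 129 EG lines, so these counts do not single out the kit. In the second set, where every array had the low-input kit, limma called 0 genes, with 1506 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0529. That 0 was not stable, with 99 genes without TGC 12-8, 59 without TGC 8-7, 30 without ES-C57BL6.9, 8 without EBRTcH3, 2 without TGC 8-8, 1 without EG-3 and 58 in the 129 lines only. The lowest value belonged to Pax6, a neural regulator (-0.82 ± 0.12). Id2 stood at -0.94 ± 0.17 there (adjusted p = 0.059), Zrsr1 at 0.68 ± 0.15 (adjusted p = 0.0935), and Klf4 at 0.56 ± 0.35 (adjusted p = 0.55). Pou5f1 stood at 0.14 ± 0.15 (adjusted p = 0.757), Sox2 at 0.17 ± 0.08 (adjusted p = 0.42), Dazl at 0.26 ± 0.31 (adjusted p = 0.799) and Ddx4 at -0.39 ± 0.11 (adjusted p = 0.189). Of the 364 first-set genes measured again, 242 had the same sign and 73 of those an unadjusted p under 0.05. Across 12058 genes the fold changes of both sets correlated with Pearson r = 0.264 and Spearman rho = 0.198. Other splits of the lines, used alike in both sets, gave a median r of 0.504, and 89 of 100 gave an r as high.

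Camera called 6 lists in the second set, with 0 member genes past the threshold in any of them. All ES arrays of this set and that of TGC 8-8 had the same extraction day, and the other EG arrays another. Day and origin are thus hardly separated in this set either. Primed-epiblast genes were lower in EG lines (adjusted p = 0.0109; adjusted p = 0.326 with an estimated correlation; 2 lower adjusted over the list alone). Trophectoderm genes (adjusted p = 0.0109; adjusted p = 0.326 with an estimated correlation) and pluripotency genes (adjusted p = 0.0114; adjusted p = 0.326 with an estimated correlation) were higher. Fibroblast feeder markers (adjusted p = 0.621 with an estimated correlation), LIF and STAT3 targets and p53 stress genes (adjusted p = 0.291 with an estimated correlation, both) were also higher, each with adjusted p = 0.0384. Adjusted over the list alone, 1 pluripotency gene and 2 LIF and STAT3 targets were higher and 0 genes of the other 3 lists passed.

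Strain separated the lines in both array sets, with origin in the fit. Cenps, a centromere protein on chromosome 4, was higher in C57BL/6 than in 129 lines by 2.43 ± 0.07 in the first set (SE, n = 12 lines, adjusted p = 1.24e-08) and by 2.60 ± 0.08 in the second. The apoptosis gene Pmaip1 (Noxa) was higher by 2.37 ± 0.15 and 1.90 ± 0.17, the bacterial sensor Nod1 by 1.85 ± 0.14 and 2.53 ± 0.13, and Rgcc by 2.03 ± 0.20 and 2.13 ± 0.19. Clmp was higher by 1.95 ± 0.34 and 2.42 ± 0.28, the class I histocompatibility gene H2-T22 by 1.99 ± 0.35 and 1.95 ± 0.32, and Txnl4a by 1.51 ± 0.16 and 1.61 ± 0.10. Lower in C57BL/6 lines were Tcstv3 (-3.43 ± 0.68 and -1.94 ± 0.46), Tcstv1 (-2.75 ± 0.63 and -2.16 ± 0.50), and Rpl39l (-3.23 ± 0.44 and -2.77 ± 0.47). So were Mmrn2 (-2.37 ± 0.34 and -2.93 ± 0.34), Fam25c (-2.32 ± 0.43 and -2.23 ± 0.40), Defa3 (-2.16 ± 0.37 and -2.47 ± 0.32) and Calml4 (-2.01 ± 0.21 and -2.17 ± 0.33). The pluripotency marker Zfp42 (Rex1) was lower by -1.98 ± 0.37 (adjusted p = 0.0178) and -1.21 ± 0.24 (adjusted p = 0.0161).

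Klf4 stood at -0.66 ± 0.39 (adjusted p = 0.392) in the first set and -0.87 ± 0.35 (adjusted p = 0.181) in the second. Pou5f1 stood at -0.59 ± 0.25 (adjusted p = 0.216) and -0.31 ± 0.15 (adjusted p = 0.263), and Sox2 at -0.08 ± 0.17 (adjusted p = 0.854) and -0.16 ± 0.08 (adjusted p = 0.308). As a list, pluripotency genes were lower in C57BL/6 lines in the second set, with 2 of 23, Zfp42 and Klf2 (-0.81 ± 0.16), down and 0 up (3 and 0 adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.796 with an estimated correlation), and were not called in the first (camera adjusted p = 0.318). In the first set fibroblast feeder markers and mesoderm genes were higher, each with camera adjusted p = 0.0492 and with adjusted p = 0.939 with an estimated correlation. Of the feeder markers 0 of 14 passed, also adjusted over the list alone, and of 18 mesoderm genes 0 were higher and 1, Hand1 at -0.31 ± 0.07, lower (3 and 1 adjusted over the list alone). In total 608 genes passed in the first set (179 higher, 429 lower; 90 over 2-fold) and 781 in the second (411 higher, 370 lower; 88 over 2-fold). The balance in the first set turned from the Cy3 channel alone, with 467 genes, 253 higher and 214 lower. Of the 608 genes 254 passed again with extraction day as a random block and 370 with sex in the fit. Of the 781 genes 333 passed again from the Cy3 channel alone. Of the 608 and 781 genes of the main fits, 121 were higher in both sets and 174 lower in both, 0 were opposite, and independent lists would share 19.2. The sets share 11 of 12 named lines, so differences between lines recur in both. With the same other split of the lines in both sets, at most 3 genes passed in both, against 295 for strain. Across genes the fold changes correlated with Pearson r = 0.812 and Spearman rho = 0.641, and 6 of 90 splits, the real one included, gave an r as high (median of the others 0.612), so this r shows line differences also. EG-1 and EG-3 are the only 129 lines among the EG lines, and the first-set count was 154 without EG-1 and 149 without EG-3, and the second-set count 288 and 217. Without ES-C57BL/6, the only C57BL/6 ES line of the first set and of doubtful identity, 427 genes passed there, of which 287 were among the 608. The second-set count was 473 without ES-C57BL6.9 and 518 without TGC 8.5-5. Sequence differences between strains under the probes were not examined. Among EG lines strain coincided with plating density, 20000 cells per cm2 for EG-1 and EG-3 and 30000 for the C57BL/6 lines, while all ES lines had 10000. In the first set no extraction day held lines of both strains. Density among EG lines, and day in the first set, thus cannot be told apart from strain.

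**Figure D3:**
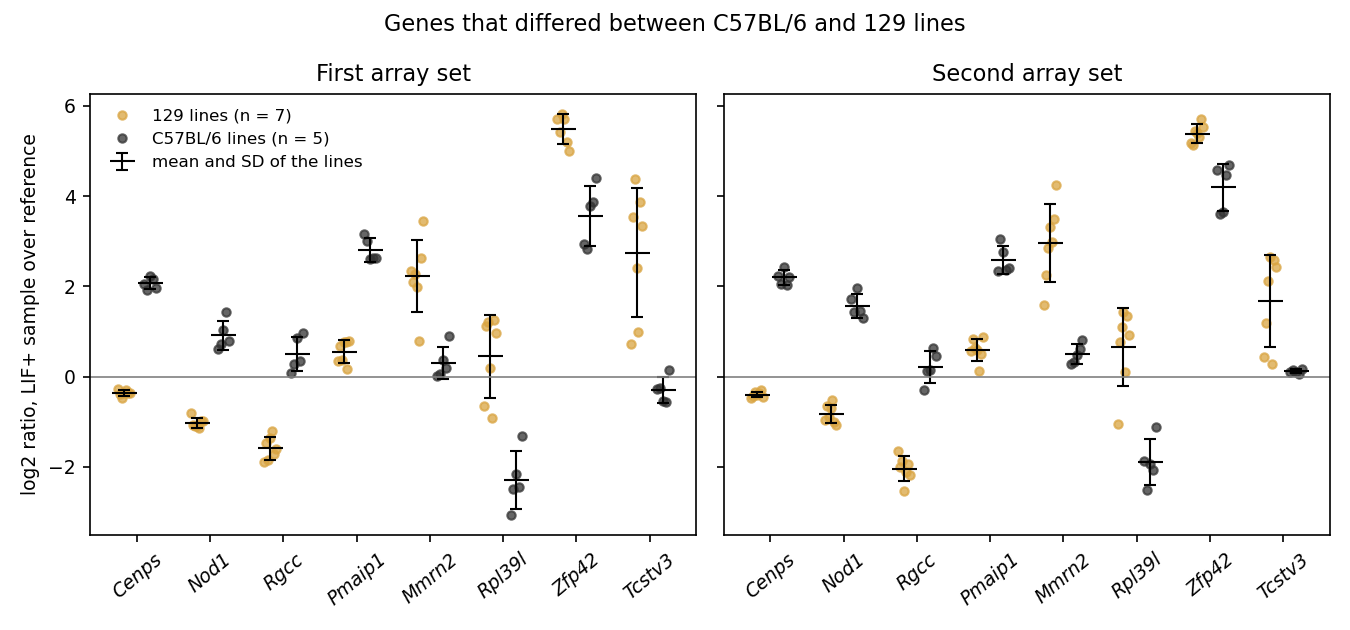
Log2 ratio of sample over reference (vertical axis) of 8 genes in LIF+ lines of 129 (yellow) and C57BL/6 (black) strain, in the first array set (left) and the second (right), with the mean and SD of the lines. Cenps was higher in C57BL/6 lines by 2.43 and 2.60 after the origin term, and Rpl39l lower by -3.23 and -2.77.

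Lines labelled female were compared with lines labelled male, with origin and strain in the fit, to ask whether sex shows in expression. The Y-linked genes Eif2s3y and Ddx3y were lower by -2.15 ± 1.17 and -1.30 ± 0.78 in the first set and by -1.09 ± 1.502 and -0.84 ± 0.94 in the second. None passed (adjusted p = 1 for both in the first set, 0.871 and 0.838 in the second). Y-linked genes as a list were lower in the first set (camera adjusted p = 0.00111; adjusted p = 0.589 with an estimated correlation), with 0 of 7 past the threshold, also adjusted over the list alone. Primed-epiblast genes were higher in the first set (camera adjusted p = 0.0252; adjusted p = 0.589 with an estimated correlation). Fibroblast feeder markers were higher in the second (camera adjusted p = 0.0131; adjusted p = 0.667 with an estimated correlation). Of these lists 0 of 10 and 0 of 14 genes were past the threshold, also adjusted over the list alone. Limma called 0 genes in either set, with 195 and 905 at an unadjusted p under 0.05. The lines labelled female were CC9.3.1, EG-3 and TGC 8-7 in the first set and CC9.3.1 and TGC 8-7 in the second. As given next, Y-linked genes ran against the labels of TGC 8-7 and TGC 12-8, so both groups mix lines with high and low Y-linked expression. The 0 genes and the list calls therefore cannot tell whether sex shows in expression.

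The Y-linked genes did not follow the sex labels in every line. Eif2s3y, the Y-linked copy of a translation initiation factor gene, stood at a log2 ratio to the reference of 2.48 ± 0.04 (SD, n = 3 arrays) in TGC 8-7, labelled female, and at -1.35 ± 0.10 in TGC 12-8, labelled male, in the first set. In the second set the values of the same lines were 2.08 and -1.78. CC9.3.1, labelled female, had -2.10 and -2.39. EG-3 had -2.14 and -2.76, under a female label in the first set and a male label in the second. Ddx3y was 1.11 in TGC 8-7 and -1.53 in TGC 12-8 in the first set, and 0.93 and -1.24 in the second. TGC 8-8, labelled male, had Eif2s3y at 0.20 and -0.10.

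**Figure D4:**
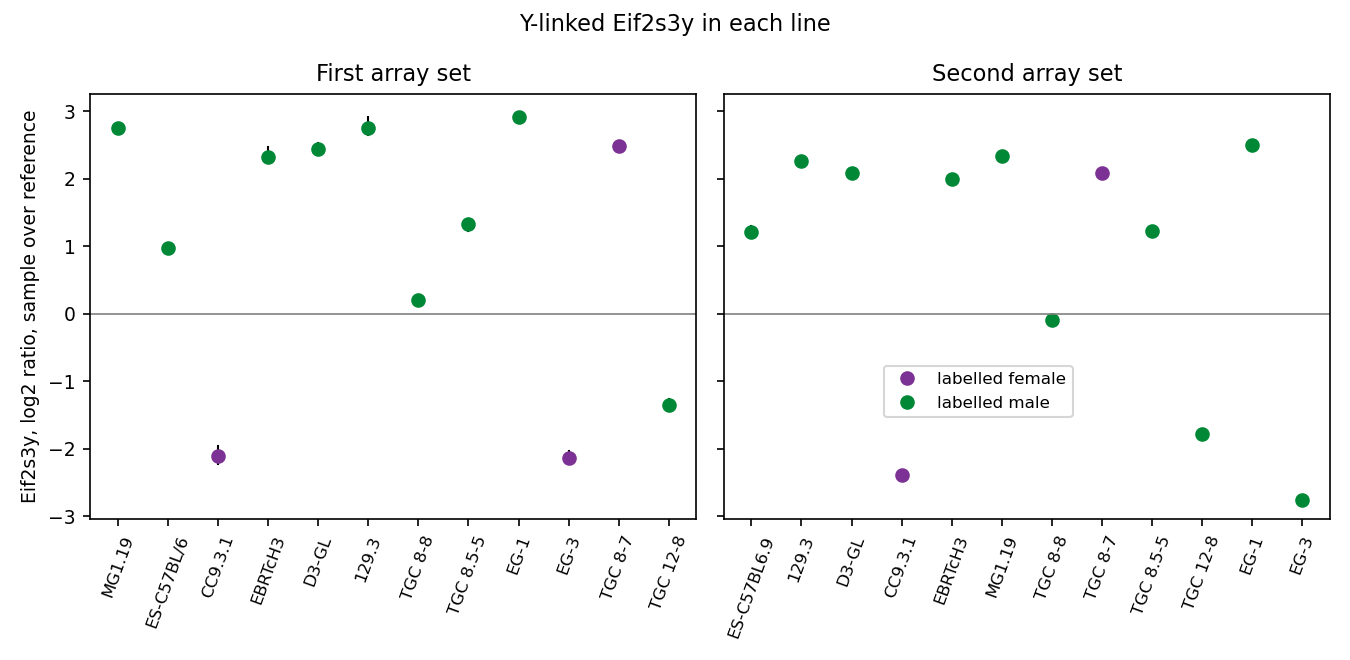
Log2 ratio of sample over reference (vertical axis) of Eif2s3y in each line of the first (left) and second (right) array set, as mean (points) and range of its arrays (lines), coloured by the sex label. TGC 8-7 carries a female label at 2.48 and 2.08, and TGC 12-8 a male label at -1.35 and -1.78.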

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

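The tests of stray signal and of an exchange by Y-linked genes were chosen after the result was seen, as were the fits with day as a random block, with strain by treatment and without the low-input EG lines. The other tests of the 3 weighed patterns were prompted by patterns already seen, and what each should give was written down before it was run. For the exchange judged by whole profiles, 1 written condition was set aside afterwards, as stated below. In 340 groups of lines or arrays 7 held a value far from the rest, where chance gives about 1 in 20, or 17.

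For the 370 genes that differed between EG and ES lines in the first set, a technical reading is open. The low-input labelling kit was used for 4 of the 6 EG lines (EG-1, EG-3, TGC 8-7 and TGC 12-8) and no ES line. Scans of all EG arrays were read by Feature Extraction on other days than those of the ES arrays. In the second set this held for every EG array but that of TGC 8-8. In the second set, where all samples had that kit, the median change of the 370 genes kept a share of 0.130 (0.51 in the first set, 0.07 in the second). The kit as the cause requires such a value. Genes picked for passing in the first set would shrink in another set for that reason too, so this share cannot single out the kit. Within the C57BL/6 EG lines the kit difference reached a share of 0.399 with 315 of 370 genes in its direction, which decides neither way. With the kit as a covariate the median was 0.30 against 0.50, the median SE rose from 0.10 to 0.13, and 0 genes passed, because the change shrank and its error grew; with day as a random block 22 passed. Leaving out the C57BL/6 ES lines, which differ between sets, raised the share only to 0.211, against these lines as the whole reason why the sets differ, yet the correlation of the sets rose from 0.264 to 0.482, so a part stays open. The labelling kit may account for a part of this pattern, while the choice of the genes, extraction day, origin, plating density and passage remain open.

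The Y-linked genes of TGC 8-7, labelled female, and TGC 12-8, labelled male, ran against their labels in both sets. An exchange of their arrays in 1 set would turn the Eif2s3y difference in that set only, and it kept its sign in both (the lower was 3.78 on the log2 scale), which argues against it. Whole profiles argue against it too, since each line matched its own name better than the other line by at least 0.618 in correlation. The written prediction had also asked that each line match its own name best. TGC 8-7 matched TGC 8-8 best (0.686, own name 0.557), so that condition was not met. It was set aside after the result, because this exchange needs a match with TGC 12-8. Against stray signal, the Y-linked genes that followed Eif2s3y over the other 10 lines, Ddx3y and Uty (r = 0.908 and 0.868), also differed, by 2.64 and 0.776, beyond 3 SD of the arrays, whereas Usp9y, Sry, Zfy1 and Zfy2 did not follow it and differed by less than the SD. Candidate explanations that stay open are a wrong sex label or an exchange of the lines before both sets, and loss of the Y chromosome in TGC 12-8; none was tested.

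Igf2r rose with retinoic acid in ES lines and not in EG lines, a difference of -1.23. With the kit by treatment in the fit the difference was -1.20 ± 0.20 (adjusted p = 0.0358), which argues against the kit, though without the 4 low-input EG lines it did not pass (-1.20, adjusted p = 0.119). The lowest 129 ES line lay 0.747 above the highest 129 EG line, and with strain by treatment the difference was -1.26 (adjusted p = 0.00125), which argues against strain. Only 1 named probe measured Igf2r, so an odd probe cannot be told apart from a change of the gene. Origin is a possible explanation as a hypothesis, while dose and density varied with origin and stay open.

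The other results that differed between ES and EG lines in their response to retinoic acid, each by the interaction test, were 90 genes in all, with Smoc2 at -1.46, Ier3 at -1.30, Pmp22 at -0.996, Ptx3 at -0.98, Rhoc at -0.85 and Hoxc9 at 0.81. With the kit by treatment 5 genes passed, 4 of them among the 90, and of the genes named here only Ptx3 (adjusted p = 0.0479). With strain by treatment 19 passed, of those named Smoc2 and Rhoc (each adjusted p = 0.0339), and without the low-input EG lines 0, so kit and strain stay open for most of the 90. A lost call does not by itself speak for kit or strain, since added terms and fewer lines also raise the error. For Igf2r the kit by treatment raised the SE from 0.14 to 0.20, while the difference went from -1.23 to -1.20. Values far from the other lines were Pim3 after LIF withdrawal in ES-C57BL/6 (-0.23; others -0.87 to -0.66) and T after LIF withdrawal in TGC 8-8 (1.69; others 0.06 to 0.56). With retinoic acid, EG-3 stood apart for Tagln (2.07; others 1.14 to 1.46) and for Igf2r (-0.52; others -0.09 to 0.07). Calml4 in TGC 8.5-5 in the second set stood at -0.92 (others -1.62 to -1.51). The median correlation with other arrays was 0.787 for the LIF+ array of EBRTcH3 (others 0.863 to 0.883) and 0.840 for the LIF- array of ES-C57BL/6 (others 0.858 to 0.869).

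Other groupings of the same lines were counted to see how often they give as many genes. For both treatments 1 of 32 sign patterns, the real one, gave as many genes in ES and EG lines. Without LIF it was 2439 against at most 1533 and 1816 against at most 284. With retinoic acid it was 5640 against at most 3868 and 5155 against at most 2631. As 1 of 32 is the smallest share this count can give, it makes chance unlikely without excluding it. For the retinoic acid interaction 2 of 100 splits, the real one included, gave at least 90 genes, which does not exclude chance in lines that differ this much. The other split gave 718, which points to a structure of the lines. That split parted MG1.19, CC9.3.1, EBRTcH3, D3-GL, EG-1 and EG-3, all 129 lines but 129.3, from the rest. Strain thus stays open for those of the 90 genes that did not pass with strain by treatment, although a lost call does not show that their change shrank. For origin in the first set only the real split of 100 gave as many genes (370 against at most 2). For strain it was 1 of 90 in each set (608 against at most 226 and 781 against at most 202). These groupings stand apart from the other splits, but the count does not tell origin from the kit or day that varied with it. Nor does it tell strain from plating density among EG lines or from day in the first set. Where 0 genes passed, every split gives as many by construction, and the count says nothing about chance: the LIF interaction (100 of 100; highest other 127, from the same split), origin in the second set (100 of 100; highest other 1) and sex in the first set (100 of 100; highest other 476, with ES-C57BL/6, TGC 8-7 and TGC 12-8 against the rest, again a structure of the lines).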

How the results depend on the processing

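Chosen after the data were seen were the fits with every passing probe, the filter at negative controls, extraction day as a random block, the second-set lines of the first extraction day, the fits without low-input EG lines or without the LIF+ array of EBRTcH3, strain by treatment, the strain correlation and the agreement of the sets under other splits. Counts below are genes past the threshold, and unless stated the cause of a change was not tested. The filter on dim probes removed nothing and its absence says nothing. Day as a block could not be fitted for treatments, because each line lies within a day and its block absorbs the day, and kit or 3-condition means do not apply to the second set. For 248 single genes in a contrast, 5916 refits gave 5528 on the same side of the threshold, 358 weaker, 26 stronger and 4 reversed. The reversed ones were Dppa5a with retinoic acid from Cy3 alone (-0.51 in ES, -0.0896 in EG lines) and Osbpl5 in ES lines (0.90 in the authors' table, 0.25 as probe mean).

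Treatments: without the replicate block, LIF withdrawal gave 421 (ES) and 152 (EG), retinoic acid 3035 and 2242, its interaction 2, since line differences then enter the error. With every probe the counts were 5102, 3586, 13289 and 11947, as more features were tested. Leaving out 1 line gave 1851 to 2554, 1331 to 1992, 5045 to 5665 and 4583 to 5316, and 0 to 0 for the LIF interaction. The retinoic acid interaction gave 35 without background correction, 9 from Cy3 alone, 5 with kit by treatment, 19 with strain by treatment and 0 without low-input EG lines, and 18 to 228 leaving out 1 line. Of these, 24 were found without MG1.19, 228 without ES-C57BL/6, 24 without CC9.3.1, 19 without D3-GL, 51 without 129.3, 18 without TGC 8.5-5, 47 without EG-1, 143 without EG-3 and 20 without TGC 12-8. Lines split so that no LIF+ array is shared gave overlaps of 381 and 202 (ES) and 105.5 and 110.5 (EG; independent lists 135, 66.7, 35.5 and 28.6), with fewer lines per contrast.

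EG against ES, first set: Cy3 alone 1, every probe 1023, kit covariate 0, mean of the 3 conditions 1077, day as random block 22, sex added 30, 129 lines only 1275, without low-input EG lines 1. Among the 129 lines every EG line had the low-input kit and every ES line the standard one, so that count cannot tell origin from kit. Leaving out 1 line gave 0 to 1049: 0 without EG-1, 0 without EG-3, 35 without D3-GL, 39 without 129.3, 47 without CC9.3.1, 135 without MG1.19, 180 without TGC 8-7, 617 without TGC 8.5-5, 646 without ES-C57BL/6 and 1049 without TGC 8-8. Second set: no background correction 16, probe mean 9, every probe 2, day as block 3, all 14 arrays 34, origin without strain 48, sex added 23, 129 lines only 58. Leaving out 1 line gave 0 to 99: 99 without TGC 12-8, 59 without TGC 8-7, 30 without ES-C57BL6.9, 8 without EBRTcH3, 2 without TGC 8-8 and 1 without EG-3. In the first set the share of higher genes from Cy3 alone was 100%, against 77.0%, but it rests on 1 call and says nothing about the balance.

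Strain, first set: every probe 1487, day as random block 254, sex added 373, EG lines only 148 (fewer samples); leaving out 1 line gave 149 to 834 (154 without EG-1, 149 without EG-3). Second set: Cy3 alone 370, every probe 2229, EG lines only 314; leaving out 1 line gave 217 to 910 (473 without ES-C57BL6.9, 518 without TGC 8.5-5, 288 without EG-1, 217 without EG-3). From Cy3 alone 54.2% of first-set calls were higher, against 29.4%. Sex: 0 to 0 in the first and 0 to 3 in the second set leaving out 1 line (3 without TGC 8-7, 1 without CC9.3.1, 1 without TGC 8.5-5). Lists: 5 called with an estimated correlation and 46 from Feature Extraction ratios, against 51. Feature Extraction ratios put the residual share at 11.0% and the Eif2s3y difference of TGC 8-7 and TGC 12-8 at 4.30, against 3.83.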

Other observations

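The genes of these paragraphs outside the rule for named genes, and the test on paternally expressed genes, were chosen after values were seen; the named genes and lists were not. Single members of 3 lists also moved with retinoic acid, and of these lists only the imprinted one in ES lines was called (camera adjusted p = 0.0436, and 0.104 in EG lines), and with an estimated correlation it was not called (adjusted p = 0.153, and 0.247 in EG lines). The imprinted gene Ndn rose by 1.28 ± 0.12 in ES and 0.86 ± 0.12 in EG lines, Sgce by 0.89 ± 0.09 and 0.76 ± 0.09, and Dlk1 by 2.21 ± 0.16 and 1.49 ± 0.16, each in 6 of 6 lines. Among p53 and stress genes Atf3 rose by 1.71 ± 0.13 and 1.22 ± 0.13, the death receptor Fas by 1.33 ± 0.12 and 0.86 ± 0.12, and Phlda3 by 1.11 ± 0.11 and 1.08 ± 0.11, with 5 of 16 up and 3 down in each origin, also adjusted over the list alone, and no call for the list (camera adjusted p = 0.266 and 0.609). Germ-cell genes went both ways, 8 of 26 up and 7 down in each origin (camera adjusted p = 0.726 and 0.751). Adjusted over the list alone the counts were 8 and 7 in ES and 8 and 8 in EG lines. Taf7l, a transcription factor of spermatogenesis, rose by 1.12 ± 0.12 and 1.20 ± 0.12, while Dppa3 fell by 1.61 ± 0.16 and 0.83 ± 0.16.

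Tcstv1 and Tcstv3, which were lower in C57BL/6 lines kept in LIF, rose with retinoic acid in ES lines as well, by 1.86 ± 0.32 (adjusted p = 4.09e-05) and 1.85 ± 0.45 (adjusted p = 0.0015), in 6 of 6 lines. For Tcstv3 the smallest rises were those of EBRTcH3 (0.53) and EG-1 (0.64) and the largest that of TGC 8.5-5 (4.42), and the difference between origins was 1.10 ± 0.64 (adjusted p = 0.547). Without LIF, Irgm1 rose by 1.34 in ES and 1.06 in EG lines, and Psmb8 by 1.69 and 1.00 (adjusted p = 0.0116 in EG lines), whereas Cxcl10 at 0.85 did not pass in EG lines (adjusted p = 0.117).

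Of 12 lines, 10 matched the line of their own name best between the array sets, over 11875 genes centred within each set. The line named ES-C57BL/6 in the first set correlated at 0.0536 with ES-C57BL6.9 of the second and at 0.695 with TGC 8-8, and TGC 8-7 correlated at 0.557 with its own name and at 0.686 with TGC 8-8. The identity of the line named ES-C57BL/6, the only C57BL/6 ES line of the first set, is thus in doubt, although the names differ and they may be 2 lines. The first-set results that rest on this line are in doubt with it. Without it 646 genes differed by origin, against 370, and 228 in the retinoic acid interaction, against 90. By strain 427 differed without it, of which 287 were among the 608 of the main fit. Without the C57BL/6 ES lines the origin contrasts of the sets correlated at 0.482 across genes, against 0.264 with them. Repeat arrays of 1 line in the second set correlated at 0.990 for ES-C57BL6.9 and 0.992 for 129.3, against 0.855 to 0.979 for other pairs.

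A hypothesis was that erased germline imprints raise paternally expressed genes in EG lines, which Zrsr1 may reflect. Over 11 measured paternally expressed genes the camera p was 0.0693 in the first set (10 of 11 higher, median 0.14) and 0.00523 in the second (9 of 11 higher, median 0.16). Without Zrsr1, which had prompted the test, p was 0.258 and 0.0305, and with an estimated correlation over all 11 genes 0.346 and 0.172 (0.554 and 0.288 without Zrsr1). The sets share 11 of 12 named lines, so the second is no independent test, and the hypothesis stays open.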
